A study of Homo sapiens with 6 samples.

How the data were processed

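RNA was sequenced from HCT116 cells, a human colorectal carcinoma line, carrying a lentiviral vector with either a negative control sequence or an inhibitor of miR-1290. Each group had 3 samples, and the grouping was taken from the sample labels. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from total RNA with an Illumina TruSeq RNA kit. Nothing in the labels says whether the 3 samples of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

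The authors deposited FPKM values (fragments scaled by transcript length and library size) for 58825 genes in the 6 samples, per the file headers. Genes without signal are listed at 0.0001 FPKM in the deposited table, and 28972 genes stood at that value in every sample. The authors' deposited table also gives a fold ratio of the group mean FPKM values, its log2, a p-value and a q-value for inhibitor against control, a direction and a significance mark. Per the submitters' processing notes, the tool Bowtie 0.12.2 and the builds hg19 and mm8 were used, with no role given for any of them. The quantification tool, the annotation release and the authors' test are not given in the sources used here.

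The table held FPKM and no read counts, so the test fixed for such values before the data were examined was applied: limma with a mean-variance trend on log2(FPKM + 1). The alternatives planned for read counts could not be run on this table. Genes with at least 1 FPKM in at least 3 samples were tested, which left 11870 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and a fold change is inhibitor minus control on the log2(FPKM + 1) scale, which understates changes of low genes. Errors of FPKM values are standard deviations over 3 samples.

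Absolute depth is unknown. Relative depth was read from genes below 0.05 FPKM, whose values move in steps of whole reads. The most frequent ratio to inhibitor replicate 1 was shared by 33 to 52 genes per sample, against 4 to 10 genes for the next ratio. By these steps the control libraries had 84.5%, 80.5% and 80.8% of the depth of inhibitor replicate 1, and inhibitor replicates 2 and 3 had 105% and 101%. The FPKM sums ranged from 329680 to 344296 per sample.

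The 43 gene lists were fixed before the data were examined, from textbook pathways, genes named earlier as miR-1290 targets, RNA quality and markers of other cell types. The 37 lists with at least 5 tested members were tested with camera from limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation, and fry from limma, were run beside it. A call lost under the estimated setting need not reflect correlated genes. The oxidative phosphorylation list had an estimated correlation of -0.0056, below the preset, and its unadjusted camera p still rose from 0.00599 to 0.0390. Member counts are given over all tested genes and adjusted over the list alone.

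Gene positions and 3′ UTR sequences came from GENCODE release 29 on GRCh38, matched by Ensembl gene identifier, which matched 58552 of the 58825 genes and 11856 of the tested ones. Positions are therefore those of that annotation and not of the authors' alignment. The longest annotated 3′ UTR of each gene was searched for sites of miR-1290 (UGGAUUUUUGGAUCAGGGA, bases 53 to 71 of the 78-base MIR1290 hairpin in the same annotation). The mature sequence was not in the sources used here; the hairpin contains it but does not show where the mature arm starts, and the sites depend on that start. A site was AAAATCCA (8mer), AAAATCC (7mer) or AAATCCA (7mer). Genes with and without a site were compared by mean log2 fold change, with camera as the test and 1000 random 7mers with 5 A/T bases as a description.

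Genes named in the text follow a rule fixed in advance. It takes MIR1290 and its host locus gene ALDH4A1, and the 10 largest rises and 10 largest falls among called genes with non-overlapping groups and a mean of at least 2 FPKM, without pseudogenes and unnamed identifiers. It also takes up to 4 called members with the smallest p from each list, every called reported target, and INPP4B, KIF13B, FOXA1, NFIX, SCAI and GSK3B by value. All other genes in the text, among them MYH9, NDUFA4, MT-CO1 and MT-ATP6, were chosen after their values were seen.

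The procedure was tested on simulated data with the real means and spreads of the 11870 tested genes. In these data 200 genes were changed, 50 at each size, all with a mean above 2 on the log2(FPKM + 1) scale. Noise was independent between genes. For inhibitor against control the procedure recovered 0% of genes changed by 0.25 on the log2 scale, 38% at 0.5, 82% at 1 and 92% at 2, with 7% false calls, and called 0 genes when none was changed. With 2516 genes called in the real data, the adjusted threshold there was easier to reach, so these shares do not describe the real calls. Alternatives comprised a pseudocount of 0.1, no filter on low values, quantile normalization, the replicate number as a block, a 2-fold threshold and leaving out each library. Median-of-ratios scaling and leaving out genes that share exons or the interferon list were added after the data were seen. Computations used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.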

Results

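Messenger RNA was profiled in HCT116 colorectal cancer cells with a lentiviral miR-1290 inhibitor (3 libraries) and with a lentiviral negative control sequence (3 libraries). MiR-1290 is a small regulatory RNA that pairs with messenger RNAs, and an inhibitor of this kind is designed to block it. The series asks how the transcriptome differs between control and miR-1290 knockdown cells. In each library 11503 to 11751 genes reached 1 FPKM. The first principal component of the 11870 tested genes held 57.5% of the variance and separated the groups. Correlations across genes were 0.977 to 0.984 within groups and 0.946 to 0.954 between groups. Inhibitor replicate 3 stood apart from the other inhibitor libraries on the second component, which held 14.9% of the variance. Mitochondrially encoded genes took 32.0% to 32.3% of the FPKM sum in control libraries and 34.6% to 35.4% in inhibitor libraries.

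The targeted RNA could not be checked in these libraries. MIR1290 (ENSG00000221662, chromosome 1, 18897071 to 18897148, minus strand, GRCh38) was listed at 0.0001 FPKM in all 6 samples. Mature microRNAs are too short for libraries of this kind, so that value does not test the labels. ALDH4A1, the metabolic enzyme gene that spans the locus (chromosome 1, 18871430 to 18902781), stood at 6.28 ± 0.725 FPKM (SD, n = 3) in control cells and 6.15 ± 2.19 in inhibitor cells (limma, Benjamini-Hochberg adjusted p = 0.863).

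Interferon genes made the widest separation between the groups. Control cells carried high levels of interferons and interferon-stimulated genes, and cells with the miR-1290 inhibitor carried little of them. The type III interferon gene IFNL1 stood at 87.4 ± 2.82 FPKM (SD, n = 3) in control cells and 0.105 ± 0.0911 in inhibitor cells. ISG15, a ubiquitin-like protein attached to other proteins during antiviral responses, was 25.4 times lower with the inhibitor, at 1652 ± 58.4 against 65.1 ± 5.69 FPKM. The type I interferon gene IFNB1, chosen after its values were seen, went from 12.6 ± 0.660 to 0.0670 ± 0.0270 FPKM.

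Of the 24 tested interferon-stimulated genes, 22 were lower under the inhibitor, 0 were higher and 2 did not pass (23 lower when adjusted over the list alone). The list had a median log2 fold change of -3.20 (camera adjusted p = 3.42e-29, and adjusted p = 0.0339 with an estimated correlation). IFIT2, IFIT1 and IFIT3, which bind viral RNA, fell by 6.21, 5.58 and 5.58 on the log2 scale. OASL, a relative of the antiviral oligoadenylate synthetases, fell from 207 ± 2.24 to 2.68 ± 0.485 FPKM (limma, Benjamini-Hochberg adjusted p = 7.57e-07). IFI27, a mitochondrial interferon-induced protein, fell from 24.1 ± 0.709 to 0.626 ± 0.0144 FPKM. IFITM1, a membrane protein that blocks virus entry, fell from 160 ± 2.35 to 5.26 ± 0.590 FPKM. It shares exon bases with IFITM2 in the annotation, so reads of these genes may have been divided between them. CCL5, a chemokine that attracts leukocytes, fell from 38.6 ± 10.2 to 0.162 ± 0.116 FPKM. Markers of leukocytes did not accompany these genes. Of 12 listed, 1 reached 1 FPKM in the control mean, and the highest, CD68, stood at 3.15 FPKM in control and 1.90 in inhibitor cells.

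**Figure D1:**
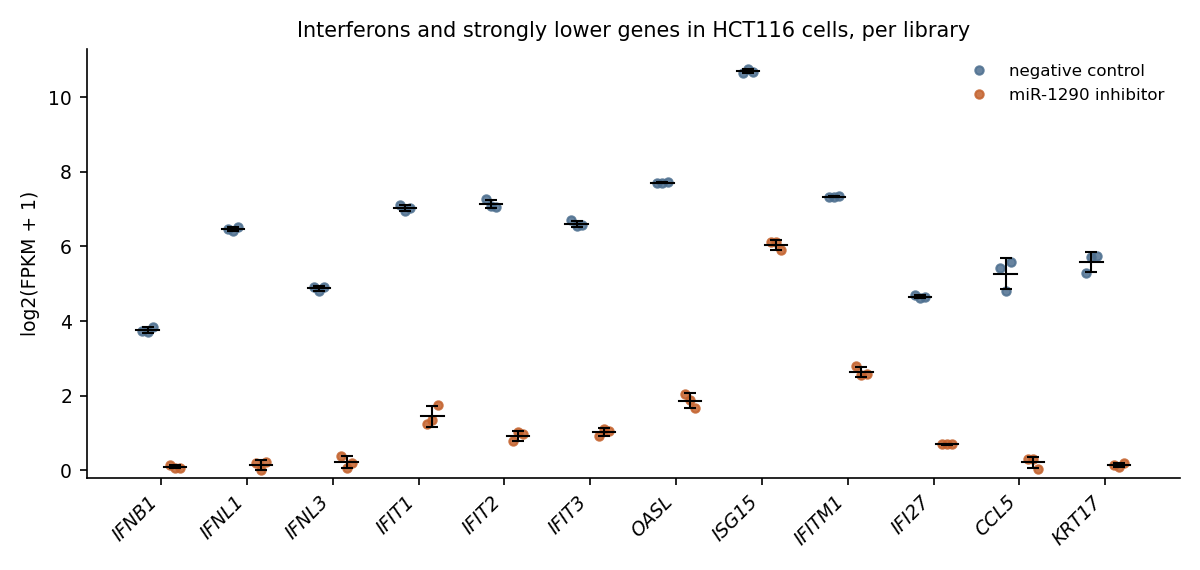
Expression of interferons, interferon-stimulated genes, CCL5 and KRT17 as log2(FPKM + 1) on the vertical axis, with 1 point per library, the mean as a line and the standard deviation (n = 3) as the error bar. All 3 control libraries lie above all 3 inhibitor libraries for each gene, and ISG15 is the gene that keeps the highest level with the inhibitor, at 65.1 FPKM.

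Across all genes, 1260 were higher and 1256 lower under the inhibitor of the 11870 tested (limma, Benjamini-Hochberg). Large changes were mostly falls. At a 2-fold change or more, 47 genes were higher and 219 lower, and at 8-fold or more 2 were higher and 27 lower. All 2516 called genes had non-overlapping groups, as did 41.2% of tested genes against 10% by chance. Leaving out any library except inhibitor replicate 3 left fewer calls, 661 to 734 higher and 774 to 857 lower, and leaving out inhibitor replicate 3 gave 1403 higher and 1582 lower.

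Most listed inflammatory and NF-κB genes were lower with the inhibitor. Interferon genes separated the same libraries, so this and the differences below cannot be told apart from the interferon response or the vector. CXCL8, which attracts neutrophils, stood at 75.4 ± 5.64 FPKM in control and 9.23 ± 1.41 in inhibitor cells, 8.17 times lower. CXCL1, a related chemokine, fell from 31.9 ± 1.97 to 7.56 ± 0.385 FPKM, and the NF-κB subunit gene RELB from 36.6 ± 1.85 to 9.69 ± 0.568. CCL20, a chemokine of lymphocytes and dendritic cells, fell by 1.94 on the log2 scale. In this list 12 of 16 tested genes were lower, 1 was higher and 3 did not pass (12 lower and 3 higher when adjusted over the list alone). The camera adjusted p was 4.55e-08, and the adjusted p was 0.0405 with an estimated correlation. The member that rose was LCN2, an iron-binding secreted protein, chosen after its values were seen, which went from 10.8 to 27.5 FPKM (limma, Benjamini-Hochberg adjusted p = 0.00126). Without inhibitor replicate 3 the higher genes numbered 3.

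Most listed genes driven by YAP, a co-activator controlled by the Hippo pathway, and its partner transcription factors TEAD were lower. Of 15 tested, 12 were lower and 0 higher, over all genes and when adjusted over the list alone (median log2 fold change -0.65, camera adjusted p = 8.68e-09, and adjusted p = 0.0405 with an estimated correlation). CCN1, a secreted matrix protein, was 3.14 times lower, at 34.8 ± 0.420 FPKM in control and 11.1 ± 0.945 in inhibitor cells. The receptor tyrosine kinase gene AXL was 2.08 times lower, and AJUBA, a junction-associated scaffold, fell by 0.77 on the log2 scale. CCN2, a matrix protein that is also on the TGF-β list, fell from 7.31 ± 0.710 to 2.28 ± 0.359 FPKM.

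Some TGF-β and mesenchymal genes were lower as well. The transcription factor gene SNAI2 went from 1.76 ± 0.385 to 0.142 ± 0.0291 FPKM (SD, n = 3), and the matrix protein gene THBS1 from 3.13 ± 0.219 to 1.21 ± 0.0664. Of 16 TGF-β genes 7 were lower and 2 higher (8 lower and 3 higher when adjusted over the list alone; camera adjusted p = 0.00885, and adjusted p = 0.165 with an estimated correlation). Of 6 mesenchymal genes 4 were lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.0198, and adjusted p = 0.182 with an estimated correlation). Of 13 secreted angiogenic regulators 7 were lower and 1, ADM, was higher (7 lower and 2 higher when adjusted over the list alone; camera adjusted p = 0.0305, and adjusted p = 0.171 with an estimated correlation). CXCL8 and THBS1 are among those 7, and each is also on another list. The higher TGF-β and mesenchymal genes numbered 1 each without inhibitor replicate 3 and 0 each without any other library. Without inhibitor replicate 3 the camera adjusted p of the mesenchymal list was 0.0777 and that of the angiogenic list 0.154.

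**Figure D2:**
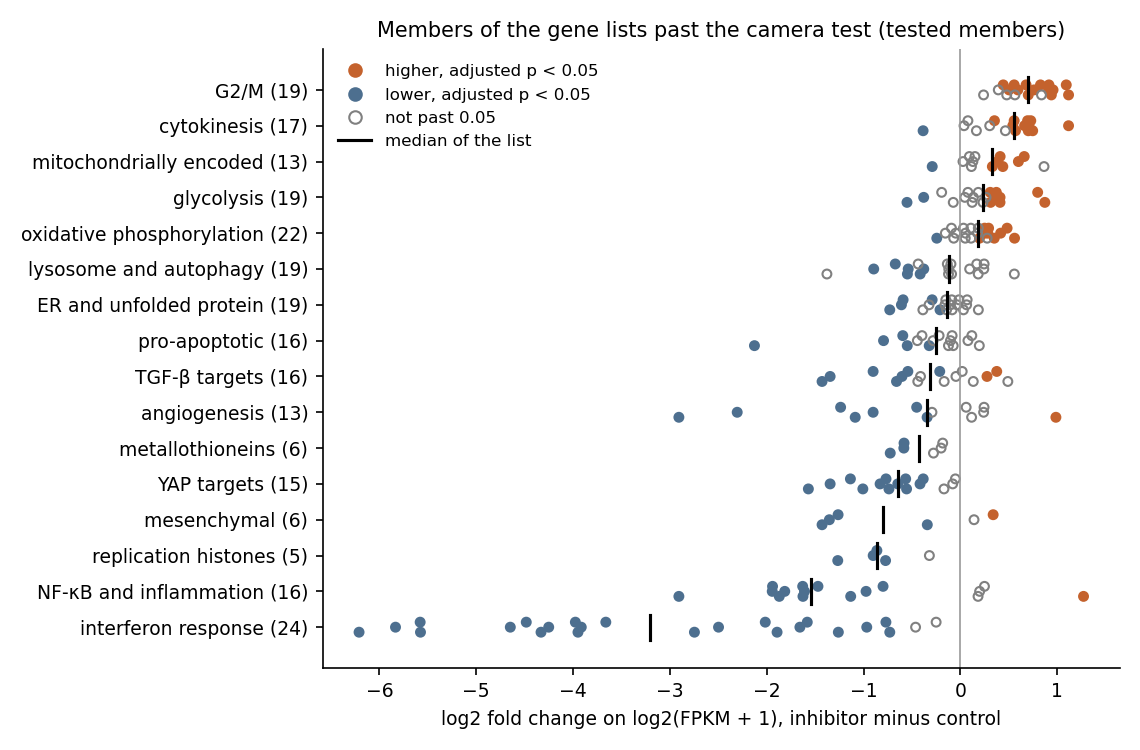
Log2 fold change (inhibitor minus control, on log2(FPKM + 1), horizontal axis) of every tested member of the 16 gene lists past the camera test at the preset correlation, 1 row per list with the number of tested members in parentheses. Filled points passed adjusted p below 0.05, open points did not, and the bar is the list median, which runs from -3.20 for interferon genes to 0.70 for G2/M genes.

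Most of the listed mitotic genes were higher with the miR-1290 inhibitor. KIF20A, a kinesin of the mitotic spindle and of cytokinesis, was 2.26 times higher, at 13.3 ± 0.135 FPKM in control and 30.1 ± 0.332 in inhibitor cells. The B-type cyclin genes CCNB1 and CCNB2 were 1.93 and 1.99 times higher. CDC20, an activator of the anaphase-promoting complex, went from 104 ± 2.27 to 197 ± 14.2 FPKM.

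Of 19 tested G2/M genes, 14 were higher, 0 lower and 5 not past the test (16 higher when adjusted over the list alone). Their median log2 fold change was 0.70 (camera adjusted p = 8.21e-10, and adjusted p = 0.0603 with an estimated correlation). Of 17 cytokinesis genes 11 were higher and 1, the myosin gene MYH9, was lower (12 higher and 1 lower when adjusted over the list alone; camera adjusted p = 1.93e-05, and adjusted p = 0.170 with an estimated correlation). CDCA8 and INCENP, subunits of the chromosomal passenger complex, rose by log2 fold changes of 0.75 and 0.73, and the kinase gene CIT by 0.70. Without control replicates 2 or 3 the higher cytokinesis genes numbered 7. KIF20A is on both lists. G1/S genes did not pass as a list, with 5 of 20 higher and 1 lower (6 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.106). The higher G1/S genes numbered 3 without control replicates 1 or 2 or inhibitor replicates 1 or 2, and 2 without control replicate 3. Among them TYMS, the thymidylate synthase targeted by fluoropyrimidines, rose from 33.4 ± 0.726 to 47.9 ± 1.03 FPKM. The G1 cyclin gene CCNE1 fell from 14.8 ± 0.740 to 8.96 ± 0.779 FPKM.

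**Figure D3:**
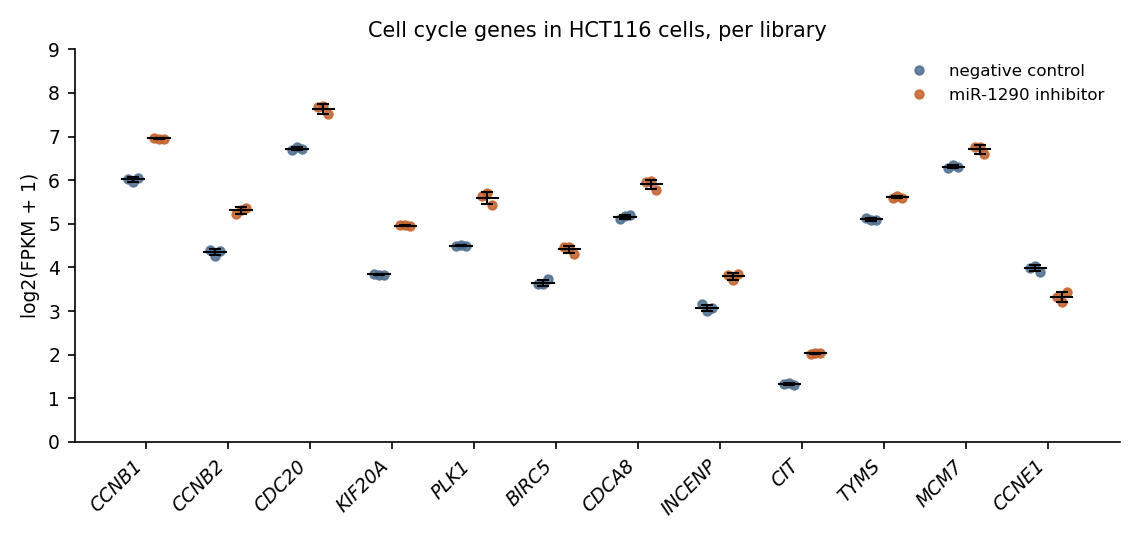
Expression of G2/M, cytokinesis and G1/S genes as log2(FPKM + 1) on the vertical axis, with 1 point per library, the mean as a line and the standard deviation (n = 3) as the error bar. The groups do not overlap for any of the plotted genes, and CCNE1 is the gene that is lower with the inhibitor, at 8.96 against 14.8 FPKM.

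Some energy metabolism genes were higher with the inhibitor, by small amounts. Of 22 nuclear-encoded oxidative phosphorylation genes 9 were higher and 1, NDUFA4, was lower (10 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0198, and adjusted p = 0.170 with an estimated correlation). Their count of higher genes was 2 without control replicates 1 or 3 or inhibitor replicates 1 or 2, 3 without control replicate 2 and 3 under median-of-ratios scaling. Their count of lower genes was 0 without any library except inhibitor replicate 3. Without genes sharing exons the list's camera adjusted p was 0.0947. SDHA, a subunit of succinate dehydrogenase, rose from 12.5 ± 0.846 to 18.9 ± 1.64 FPKM. Of 19 glycolysis genes 8 were higher, among them PGK1 and GPI with log2 fold changes of 0.31 and 0.41, and 2 were lower (9 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.0305, and adjusted p = 0.527 with an estimated correlation). The count of higher genes was 4 without control replicates 1 or 3 or inhibitor replicates 1 or 2, and 5 without control replicate 2. Without control replicate 2 the count of lower genes was 1. The list's call was lost without control replicate 3 and without inhibitor replicates 1 or 2 (camera adjusted p = 0.0683, 0.0811 and 0.0791).

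Of the 3 lists fixed as signs of RNA quality or library selection, 2 passed the camera test and nuclear non-coding RNAs did not (0 of 8 called, camera adjusted p = 0.782). Of 13 mitochondrially encoded mRNAs, which also follow mitochondrial content, 6 were higher and 1, MT-CO1, was lower (7 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.00542, and adjusted p = 0.50 with an estimated correlation). The lower ones numbered 0 without control replicate 2 and with no filter on low values. MT-ND1, a subunit of respiratory complex I, rose from 3112 ± 4.11 to 4924 ± 372 FPKM. Under quantile normalization 3 of these mRNAs were higher and 2 lower, with a camera adjusted p of 0.583 for the list and a limma adjusted p of 0.107 for MT-ND1. Of 22 genes listed as replication-dependent histones, a class whose mRNAs mostly lack poly(A) tails, 5 passed the filter. Of these 4 were lower, also when adjusted over the list alone (median log2 fold change -0.86, camera adjusted p = 0.00119, and adjusted p = 0.171 with an estimated correlation). Whether the transcripts of these 4 genes carry tails was not tested, so their fall need not reflect library selection. HIST1H1C, a linker histone, fell from 43.7 ± 5.61 to 17.5 ± 1.16 FPKM.

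Stress, degradation and cell death genes fell in part. Of 16 pro-apoptotic genes 5 were lower and 0 higher, over all genes and when adjusted over the list alone (camera adjusted p = 0.00628, and adjusted p = 0.165 with an estimated correlation). Without inhibitor replicate 3 the lower ones numbered 8. PMAIP1, which encodes the BH3-only protein NOXA, fell from 51.5 ± 4.64 to 12.4 ± 8.25 FPKM. Of 19 endoplasmic reticulum and unfolded protein genes 5 were lower and 0 higher (6 lower when adjusted over the list alone; camera adjusted p = 0.0246, and adjusted p = 0.171 with an estimated correlation). Without genes sharing exons its camera adjusted p was 0.0615, and without control replicates 1, 2 or 3 or inhibitor replicate 1 the lower genes numbered 3. HSPA5, the main chaperone of that compartment, fell from 511 ± 21.3 to 335 ± 19.1 FPKM. Of 19 lysosome and autophagy genes 6 were lower and 0 higher (8 lower when adjusted over the list alone; camera adjusted p = 0.0377, and adjusted p = 0.171 with an estimated correlation). SQSTM1, an autophagy receptor, fell from 124 ± 5.49 to 66.2 ± 4.13 FPKM. This list's call was lost without control replicates 2 or 3 and without inhibitor replicates 1 or 3 (camera adjusted p = 0.0698, 0.0976, 0.0596 and 0.0632). It was also lost under median-of-ratios scaling, without genes sharing exons and with the replicate number as a block (camera adjusted p = 0.0508, 0.0524 and 0.0522). Of 6 metallothionein and zinc genes 3 were lower (5 when adjusted over the list alone; camera adjusted p = 0.00628, and adjusted p = 0.165 with an estimated correlation). The lower ones numbered 1 without control replicates 2 or 3 or inhibitor replicates 1 or 2, and 2 without control replicate 1 or inhibitor replicate 3. MT1E, a metal-binding protein, fell from 230 ± 9.41 to 139 ± 3.99 FPKM.

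The other lists did not pass the camera test. With no filter microRNA machinery, G1/S and integrated stress genes passed (camera adjusted p = 0.0169, 0.0169 and 0.0413), as did microRNA machinery without control replicate 1 or inhibitor replicate 2 (0.0478 and 0.0401). Immediate early and ERK feedback genes went both ways, with 7 of 21 higher and 7 lower. DUSP6, a phosphatase that acts on ERK, rose from 37.9 ± 1.07 to 75.1 ± 6.83 FPKM, and JUN, an AP-1 subunit, fell from 47.4 ± 1.13 to 24.9 ± 1.02. Among p53 targets 5 of 20 were higher, among them the cytokine gene GDF15 with a log2 fold change of 0.63, and 6 were lower, among them AEN at -0.78. Integrated stress response genes had 8 of 21 higher and 3 lower, and DDIT4, an inhibitor of mTORC1 signalling, rose from 192 ± 3.86 to 356 ± 5.76 FPKM. NRF2 genes had 2 of 16 higher, including NQO1 with a log2 fold change of 0.69, and 6 lower, including HMOX1, which fell from 18.6 ± 1.14 to 7.58 ± 0.797 FPKM. Hypoxia genes had 2 of 16 higher and 2 lower, and Notch genes 3 of 12 higher and 2 lower, with HES1 at 0.98 and HES4 at -1.63. Wnt targets had 2 of 13 higher and 4 lower, and DKK1, a secreted Wnt antagonist, was 8.34 times lower with the inhibitor, from 108 ± 3.91 FPKM in control cells. The epithelial list had 2 of 19 higher and 3 lower, fatty acid synthesis 1 of 14 and 3, cholesterol 1 of 23 and 2, and heat shock 1 of 13 and 1. The anti-apoptotic list had 1 of 8 higher and 2 lower, fluoropyrimidine and efflux genes 2 of 17 and 4, and stemness genes 0 of 9 and 1. Ribosomal proteins had 3 of 22 higher and 1 lower, and ribosome biogenesis genes 2 of 20 and 1. PI3K and AKT regulators had 3 of 16 higher and 0 lower. Among these 3 are PIK3R2, whose values are uncertain as described below, and AKT1 and MTOR, whose calls were lost under 8 and 9 of 11 alternatives. MicroRNA machinery genes had 3 of 15 higher and 0 lower, with DGCR8, the partner of DROSHA in microRNA processing, at a log2 fold change of 0.46. Nuclear non-coding RNAs had 0 called of 8. When adjusted over the list alone, higher and lower counts were 8 and 7 for immediate early, 5 and 6 for p53, 9 and 4 for integrated stress, 4 and 7 for NRF2, 3 and 3 for hypoxia and for Notch, and 3 and 5 for Wnt genes. They were 2 and 3 for epithelial, 1 and 3 for fatty acid, 1 and 2 for cholesterol, anti-apoptotic and stemness, 1 and 1 for heat shock and ribosome biogenesis, and 2 and 4 for fluoropyrimidine and efflux genes. They were 3 and 0 for ribosomal protein, 1 and 0 for PI3K and AKT, 4 and 0 for microRNA machinery and 0 and 0 for nuclear non-coding genes. Higher NRF2 genes numbered 4 without inhibitor replicate 3 and 1 without control replicates 1 or 2 or inhibitor replicates 1 or 2. Lower NRF2 genes numbered 3 without control replicates 2 or 3 or inhibitor replicates 1 or 2, and higher immediate early genes 4 without control replicate 2. Higher PI3K and AKT genes numbered 1 without any library except inhibitor replicate 3, and higher ribosomal protein genes 1 without control replicate 2 or inhibitor replicate 2. Lower epithelial genes numbered 5 without control replicate 1 or inhibitor replicate 3, and lower cholesterol genes 5 and lower ribosome biogenesis genes 3 without inhibitor replicate 3. The other counts of 0, 1 or 2 in these lists moved by at most 1 when a library was left out. Camera adjusted p over these lists ran from 0.0706 for microRNA machinery to 0.974 for hypoxia, p53 and Notch genes, and the median of Notch genes, -0.08, lay opposite to the direction of the test. The anti-apoptotic list had a median of 0.02 and a mean of -0.17. Colon differentiation markers had 2 tested members with 0 called. Among markers of other cell types 1 gene was called, ACTA2, which fell from 3.05 ± 0.298 to 1.98 ± 0.372 FPKM with its call lost under 8 of 11 alternatives, and the highest was EGFL7 at 22.2 FPKM in control and 19.7 in inhibitor cells.

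Genes named earlier as miR-1290 targets did not move together. Of 13 tested, 3 were higher, 1 lower and 9 not past the test (4 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.772). The kinase gene GSK3B rose from 4.68 ± 0.431 to 6.70 ± 0.733 FPKM (SD, n = 3), the cyclin gene CCNG2 from 1.33 ± 0.211 to 2.31 ± 0.401, and the transcription factor gene NFIX from 2.42 ± 0.782 to 4.81 ± 1.09. IRF2, a transcription factor of the interferon system, fell from 3.33 ± 0.0932 to 2.32 ± 0.453 FPKM. The higher targets numbered 0 without control replicate 2 and 1 without control replicate 3 or inhibitor replicates 1 or 2. The lower ones numbered 2 without inhibitor replicate 3 and 0 without any other library. These 4 calls were lost under 5, 5, 6 and 8 of 11 alternatives. INPP4B, a lipid phosphatase, had a log2 fold change of -0.16 (limma, Benjamini-Hochberg adjusted p = 0.292) and KIF13B, a kinesin, of -0.01 (adjusted p = 0.952). FOXA1 and SCAI lay below the filter, at 0.110 and 0.353 FPKM in control and 0.201 and 0.401 in inhibitor cells. The list had a median of -0.01, a mean of 0.07 and an upward camera direction.

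Transcripts with a match to the miR-1290 seed did not shift as a class. Of 10276 tested genes with an annotated 3′ UTR, 2316 carried AAAATCCA, AAAATCC or AAATCCA. Their mean log2 fold change was -0.018, against -0.026 for the 7960 genes without a site, a difference of 0.0077 that did not pass camera at 0.05. Among genes with a site 226 were higher and 217 lower, and without one 870 were higher and 903 lower. The 631 genes with the 8mer differed by -0.013 from all other genes with a 3′ UTR, including those with a 7mer only. That difference did not pass either. Of 1000 random 7mers with the same A/T content, 512 gave a higher difference and 488 a lower one, and 95% of them lay between -0.016 and 0.032.

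**Figure D4:**
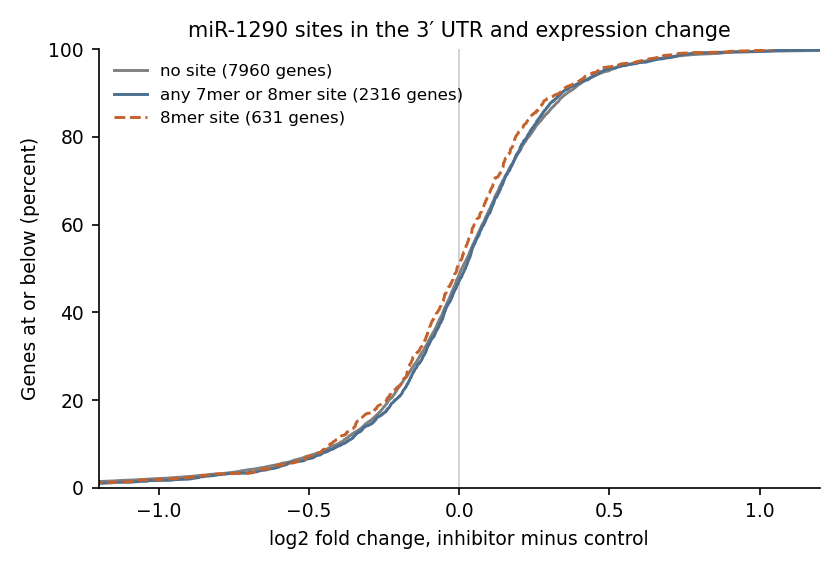
Cumulative share of genes (percent, vertical axis) at or below each log2 fold change (inhibitor minus control, horizontal axis) for 7960 genes with no miR-1290 site in the longest 3′ UTR, 2316 with any 7mer or 8mer site and 631 with an 8mer site. The curves lie close together, and the mean difference between genes with any site and with none is 0.0077.

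The rise with the largest log2 fold change by the fixed rule was PIK3R2, a regulatory subunit of phosphoinositide 3-kinase (ENSG00000105647, chromosome 19, 18153118 to 18170540, plus strand, GRCh38). It stood at 0.148 ± 0.0797 FPKM in control and 17.0 ± 0.399 in inhibitor cells. AC007192, an overlapping gene model on the same strand (18153158 to 18178117) that spans PIK3R2 and IFI30, moved the other way, from 8.19 ± 0.482 to 0.0205 ± 0.00206 FPKM. IFI30, a lysosomal thiol reductase gene, stood at 34.3 ± 0.937 and 32.9 ± 1.88 FPKM. Reads of PIK3R2 and AC007192 cannot be separated where they share exons, so the values of both are uncertain.

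**Figure D5:**
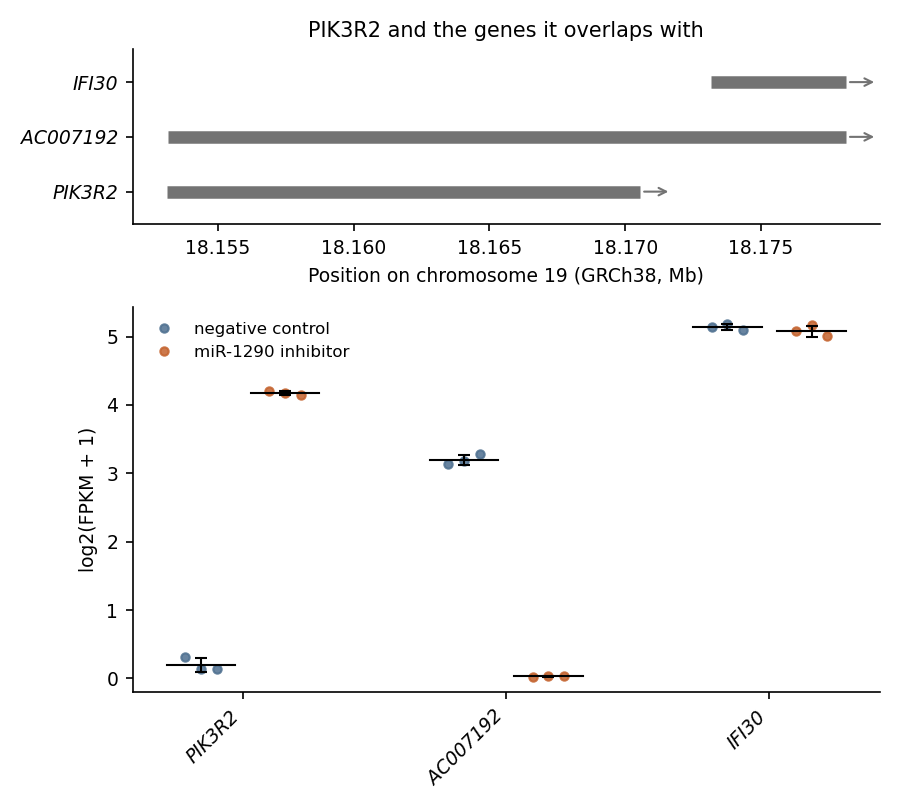
Upper part, extents of PIK3R2, AC007192 and IFI30 on chromosome 19 (GRCh38, Mb, arrows give the strand); lower part, log2(FPKM + 1) per library with the mean as a line and the standard deviation (n = 3) as the error bar. PIK3R2 is at 0.148 FPKM in control and 17.0 in inhibitor cells, while AC007192 is at 8.19 and 0.0205.

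The remaining large rises were smaller. DHRS3, a retinaldehyde reductase, was 3.82 times higher, at 4.64 ± 0.0998 FPKM in control and 17.7 ± 1.21 in inhibitor cells (limma, Benjamini-Hochberg adjusted p = 3.26e-05). CEMIP, a hyaluronan-degrading protein, was 3.25 times higher, and the long non-coding RNA gene DANCR 3.42 times higher. The mitochondrial tRNA genes MT-TQ and MT-TH rose from 4.66 ± 1.08 to 15.8 ± 2.21 and from 23.8 ± 2.76 to 64.5 ± 5.37 FPKM. Both genes are short (4329 to 4400 and 12138 to 12206 on the mitochondrial genome). Their values may hold reads of longer or neighbouring transcripts, so they do not show that mature tRNA levels changed. CHURC1-FNTB, a readthrough gene sharing exons with CHURC1 and FNTB, went from 0.959 ± 0.128 to 7.12 ± 3.34 FPKM. CHURC1 went from 6.80 to 5.09 and FNTB from 9.07 to 10.4 FPKM. ZNF664, a zinc finger gene that shares exons with RFLNA and AC068790, went from 6.15 ± 1.88 to 19.9 ± 2.90. RFLNA went from 0.0279 to 0.00767 and AC068790 from 0.618 to 0.0593 FPKM. Reads may have been divided between genes that share exons, so these 2 rises are uncertain. ADNP, a homeobox protein gene, went from 2.26 ± 0.794 to 7.96 ± 3.55, and its call was lost under 3 of 11 alternatives. CHAMP1, a chromosome alignment protein gene, went from 1.84 ± 2.26 to 7.58 ± 0.351, with 4.45 FPKM in control replicate 1, and its call was lost under 8 of 11. Among the falls outside the interferon list, KRT17, a keratin of stratified epithelia, went from 47.2 ± 8.17 to 0.107 ± 0.0387 FPKM, and IFNL3, another type III interferon, from 28.3 ± 1.15 to 0.168 ± 0.137.

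The authors' deposited table marks 913 genes, 287 up and 626 down. By the authors' deposited table a mark goes with a p below 0.05 and at least a 2-fold ratio, and 156 marked genes have a q of 0.05 or more. Of these 913 genes 389 fell below the filter used here, and 445 of the 524 tested ones were called by limma in the same direction. For IFNL1 the authors' deposited table gives a log2 ratio of -9.70, for ISG15 -4.67 and for PIK3R2 6.85.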

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

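Median-of-ratios scaling and leaving out genes that share exons or the interferon list were chosen after seeing the data. The counts of higher and lower genes stayed within 1.5 times of 1260 and 1256 with a pseudocount of 0.1, no filter, quantile normalization, median-of-ratios scaling and without genes sharing exons or the interferon list, at 864 to 1384 higher and 1067 to 1263 lower. Leaving out the interferon list kept 11846 of the 11870 tested genes, so its counts had to stay close. That setting does not test whether other calls depend on the interferon response. A 2-fold threshold gave 47 higher and 219 lower, by its own construction. With 5 libraries in place of 6, the counts were 734 higher and 857 lower without control replicate 1, 668 and 774 without control replicate 2, and 675 and 793 without control replicate 3. They were 675 and 850 without inhibitor replicate 1, 661 and 811 without inhibitor replicate 2, and 1403 and 1582 without inhibitor replicate 3.

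Same-numbered control and inhibitor libraries did not deviate together (r = -0.068, 0.031 and -0.108 across genes). Differently numbered libraries ran from r = -0.156 to 0.191. These values gave no sign of pairing but cannot exclude shared handling. With the replicate number as a block, 519 genes were higher, 711 were lower and 15 lists passed, without the lysosome and autophagy list.

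Of the 37 tested lists, 16 passed camera at the preset correlation and 3 of these also passed with an estimated correlation. Fry, which tests a different question, was passed by 27 of the 37. Without 1 library 13 to 17 lists passed. List values from the settings other than the 2-fold threshold and leaving out genes that share exons numbered 443. Of these, 426 kept their side of the threshold, 12 lost it, 5 gained it and 0 reversed. A reversal was counted only where a value passed in at least 1 of the settings compared. Among the 426, 18 medians changed sign without passing. Over 1562 values of 142 named genes 187 lost the call, 0 reversed and 6 changed sign without passing. Of the 20 top genes 18 to 20 kept their calls.

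The seed match difference of 0.0077 changed sign to -0.013 with 8mers only, to -0.0029 after removing UTR length and A/T content and to -0.010 in genes above the median of mean expression. It ran from -0.030 to 0.028 without 1 library. None of these passed camera, and the cause was not tested.

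The tests planned for read counts were not run because the table holds FPKM. Absolute depth is unknown, which limits what can be said of genes near the floor.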

Other observations

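The gene groups in the next 2 paragraphs, the mitochondrial tRNAs, MT-ATP6 and the tests on leukocytes, on G2/M against G1/S genes and on PIK3R2 were chosen after the results were seen. Most chosen genes of class I antigen presentation were lower with the inhibitor. Of 13 tested, 11 were lower and 0 higher, with a median log2 fold change of -0.91. TAP1, a peptide transporter, went from 45.5 ± 1.53 to 15.4 ± 1.95 FPKM (SD, n = 3). PSMB9, an immunoproteasome subunit, went from 15.3 ± 0.782 to 3.03 ± 0.175 FPKM.

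Of the genes chosen for stratified epithelium and its basement membrane 10 of 10 tested were lower, with a median log2 fold change of -1.30. Since they were picked from these values, that count is no independent evidence of a direction. LAMB3, a laminin chain, went from 108 ± 4.01 to 17.5 ± 1.42 FPKM and KRT17 from 47.2 ± 8.17 to 0.107 ± 0.0387. Among gene ontology terms in the deposited annotation, keratinization had 13 of 25 members lower and 0 higher (camera adjusted p = 0.000387, and adjusted p = 0.864 with an estimated correlation). Epidermis development had 12 of 29 lower and 5 higher and did not pass (camera adjusted p = 0.0542, and adjusted p = 0.864 with an estimated correlation). Of 1701 terms 34 passed upward and 29 downward, and 0 passed with an estimated correlation. The kinetochore term had 25 of 94 members higher and 1 lower (camera adjusted p = 0.00012, and adjusted p = 0.864 with an estimated correlation).

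Values over mitochondrial tRNA genes went both ways, and for the reason given for MT-TQ and MT-TH they do not measure mature tRNAs. Of 22 tested, 12 were higher, 5 lower and 5 not past the test. MT-TC, MT-TN, MT-TA and MT-TY, neighbours on the minus strand between 5587 and 5891, fell by 0.68, 0.61, 0.58 and 0.39 on the log2 scale. MT-TH, MT-TS2 and MT-TL2, neighbours on the plus strand between 12138 and 12336, rose from 23.8 to 64.5, from 28.3 to 74.3 and from 32.6 to 85.2 FPKM. MT-ATP6 stood at 3720 and 4013 FPKM in inhibitor replicates 1 and 2 and at 11310 in inhibitor replicate 3.

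For the counts of 1260 higher and 1256 lower genes, the highest of the other splits of the 6 samples gave 2 genes in one direction. The real split was the 1 split of 10 with as many, and 10 splits are too few for a share below 0.1.

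The fall of the interferon list was set against sample-wide scaling and against leukocytes in the control cultures. Under quantile normalization 22 members were lower. The median log2 fold change was 0.012 over all tested genes and -3.20 over the list, a gap that argues against scaling. In the control mean 1 of 12 leukocyte markers reached 1 FPKM, which argues against leukocytes. A candidate explanation is that the control vector or its handling induced interferon and the inhibitor vector did not, and another is an effect of miR-1290 inhibition itself. Each group carried a single kind of vector and no cells without vector were analysed here, so these explanations were not tested and remain open. The same limit holds for every other difference between the groups, among them the NF-κB, YAP, class I and G2/M genes.

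The rise of the G2/M list was set against scaling, a GC content and length trend, and an equal rise of all cell cycle genes. Under quantile normalization 14 of 19 members were higher. After the GC content and transcript length trend was removed from each library 17 of 19 were higher. These counts argue against scaling and against such a trend. The mean log2 fold change of G2/M genes exceeded that of the 20 G1/S genes by 0.59 (0.71 against 0.12, permutation p = 1e-05 over genes, the smallest that 100000 resamples can give). That p treats genes as independent and does not measure the spread between libraries. When any 1 library was left out, the G2/M median was at least 0.589 and the G1/S median at most 0.196. These values argue against an equal rise of the listed genes. More cells in mitosis with the inhibitor may account for this. A mitotic index or DNA content would test that hypothesis, and these data cannot. Growth rate or density at harvest, which the labels do not give, stays open. So does the interferon response of the control cells, which differed between the same libraries.

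The opposite moves of PIK3R2 and its overlapping gene AC007192 may reflect reads assigned to one or the other gene model. FPKM times transcript length summed over both genes differed between groups by 0.69 on the log2 scale, against 6.85 for PIK3R2 alone, which is consistent with reassigned reads and leaves a 1.61-fold higher sum in inhibitor cells. A switch between the transcripts themselves would give the same values and was not tested. Across the 24 pairs of called genes that share exons 10 went opposite ways, against 12 for random pairs (one-sided permutation p = 0.841 for more and 0.277 for fewer), so that test left open whether such reassignment is general.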
